A study of Homo sapiens with 11 samples.

How the data were processed

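The series covers A549 and H1299 lung cancer cells. Each line has 1 RNA-seq library of cells with an shRNA against GFP (shGFP) and 2 of cells with an shRNA against METTL3 (shMETTL3, numbered 1 and 2). m6A immunoprecipitation gave 2 peak lists for A549 and 1 for H1299. The 2 input samples have no table or peak list of their own, and were not analysed here. Per the labels' protocols, poly(A) RNA was selected, fragments were pulled down with an anti-m6A antibody from Synaptic Systems, and libraries were made with a TruSeq Stranded mRNA kit. The submitters' processing notes name TopHat, Bowtie and the hg19 build without versions or roles. The read counter, gene annotation and strand setting were not given in the sources used here.

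The deposited RNA tables hold a signal per gene and library. Tested on the values, each is a whole number of reads that the authors divided by 1 factor per library, and 100% of values fitted this within their rounding. The factors were 3.8, 2.8 and 3.2 for A549 shGFP, library 1 and library 2, and 5.1, 4.5 and 5 for H1299. Values carry 2 decimals in A549 and 1 in H1299, which still points to a single whole number of reads. What the factors were based on was not given in the sources used here. Multiplying back gave 19966206, 14447379 and 16504759 reads in A549 genes and 26351309, 23099169 and 25443078 in H1299 genes. The A549 knockdown columns are headed shMEL and a number, and were matched by that number to the only A549 knockdown samples. The tables list 21316 genes (A549) and 20915 (H1299), of which 19806 are in both. Of the names, 87.3% in each table match a current or older human gene symbol. Spreadsheet dates replaced 27 names in A549 and 25 in H1299, and 2 and 1 names were repeated. Genes with date names stayed in the tests within a line, were left out of tests across lines and were never named.

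The deposited peak lists give a start, an end and, for A549 immunoprecipitation 2 and H1299, a score. The scale of the score was not given in the sources used here; A549 immunoprecipitation 1 has the score 0 throughout and was used whole. Peak names in the files start with MACS, while its version, thresholds and use of the input were not given in the sources used here. Coordinates are printed on hg19 with the first base as 1.

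Fold changes were differences of log2(value + 1), which understate changes of genes with low values. Genes with a mean of at least 1 over the libraries of a line entered. limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) compared shMETTL3 with shGFP in each line, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Each line leaves 1 residual degree of freedom, and the lone shGFP library is assumed to vary like the knockdown libraries. The labels do not say whether the numbers 1 and 2 stand for hairpins or replicates, nor whether cultures were separate. The p-values therefore cover only the spread between these libraries. A fit of all 6 libraries with line as a term tested both lines together, and an interaction term tested differences between lines. A rule of size, with no test, counted genes at least 2-fold changed in the same direction in libraries 1 and 2. limma's camera, with an inter-gene correlation of 0.01, tested 29 gene lists written before the files were opened, where at least 5 members were measured. Of these, 1 was tested with the others and is not reported here. An adjustment over the list alone means Benjamini-Hochberg over its members.

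The design written before the files were opened foresaw FPKM or counts. The tables hold neither, so limma on log2 values was kept, and edgeR 4.0.16 (quasi-likelihood, recovered reads) was added after seeing the data. Also added then were a minimum mean of 20, camera on both lines together and on the interaction, and every comparison of the numbers 1 and 2. Alternatives fixed earlier were a pseudocount of 0.1, a minimum mean of 5 or none, median centring, no intensity trend, all 6 libraries in the fit, a 1.5-fold rule, an estimated inter-gene correlation, and leaving out each knockdown library. For tests within a line, the last 2 were run in the fit that holds both lines, on genes kept in both. The fit and the members of a list then change as well, such as 13 epithelial genes in place of 19 in A549. The median log2 ratio to shGFP, which a scaling error would move, was 0.02 and -0.01 for A549 libraries 1 and 2, and 0.09 and -0.04 for H1299.

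The code was tested on simulated data of the same depth, in which genes with a mean of at least 20 were set to change. In A549 the limma test found 16.4% of genes set to change 2-fold, 80.6% of those at 4-fold and 98.5% at 8-fold, with 5 false calls. In H1299 it found 0, 37.3 and 78.8%, with 0 false calls. The fit of both lines found 100% at each size, with 7 false calls, but those data held no difference between the numbers 1 and 2. Camera called the list that had been shifted, and also 2 of 27 unshifted lists, so that a called list may be a chance call more often than the threshold implies. With no change simulated, the rule of size still counted 187 higher and 117 lower genes in A549, and 44 and 26 in H1299. The spread simulated within a line was estimated from the difference of libraries 1 and 2. It thus holds any difference between the numbers, so these counts can be too high.

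Peaks were compared with bedtools 2.31.1, where an overlap of 1 bp counted as shared; the lists give no informative strand, so none was used. The share expected by position came from 100 random shifts of each peak by 10 to 100 kb. Without an annotation the shifts could not be kept within transcripts. The expected share can therefore be too low for lists that both lie in transcripts. Percentages carry 95% binomial intervals. Alternatives were a 50% reciprocal overlap and the peaks at or above the median score of each list. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for the peak tables and figures.

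Genes were named by a rule written before the files were opened: METTL3, 4 targets known from the study, and genes of m6A writers, readers and erasers. To these come up to 12 genes with the largest increase and decrease per line, filled from the rule of size where too few passed the test, and 10 genes with the largest change in the same direction in both lines. For each list the rule asked for 2 to 4 members with the largest change, but the text names fewer or none for some lists. Copies of gene families, read-through transcripts and genes without a symbol were skipped. The 10 peaks with the highest score were taken per list with scores. The genes named for a difference between the numbers 1 and 2 were chosen after seeing their values. No hg19 annotation or genome was at hand, so that peaks could not be given to genes. Methylated genes, their change in level, peak position in transcripts and sequence motifs were not analysed here.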

Results

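METTL3, the catalytic subunit of the mRNA m6A methyltransferase, was lower in all 4 knockdown libraries. In A549 it stood at 557 in the shGFP library and at 231 and 232 in shMETTL3 libraries 1 and 2, or 41.6 and 41.7% of the control. In H1299 it stood at 271 and at 123 and 100.2, or 45.4 and 36.9%. By limma the log2 change was -1.26 (SE 0.19) in A549 and -1.28 (SE 0.25) in H1299, with an adjusted p of 1 over all genes in each line. Adjusted over the list of m6A genes alone, p was 0.0395 in A549 and 0.0730 in H1299, and neither side of the threshold held throughout. In A549 the call was lost with no filter (adjusted p = 0.103), no intensity trend (0.216) and library 1 or 2 left out (0.122 and 0.124). In H1299 it was gained with median centring (adjusted p = 0.000580), all 6 libraries in the fit (0.0152), a mean of at least 5 (0.0127) or 20 (0.000763), and library 1 left out (0.0288). Over both lines the change was -1.27 (SE 0.13), with an adjusted p of 0.139 over all genes and 0.000214 over the list alone. edgeR on the recovered reads, added after seeing the data, gave an FDR of 0.00172 in H1299, where METTL3 passed.

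The other genes of m6A writing, reading and removal stayed near their control level. METTL14, the partner of METTL3 in the writer complex, had log2 changes of 0.07 in A549 and 0.32 in H1299, and WTAP, which anchors that complex, 0.20 and 0.34. The writer component KIAA1429 (now VIRMA) had -0.13 and 0.26, and the second methyltransferase METTL16 -0.16 and 0.12. The demethylases FTO and ALKBH5 had 0.09 and 0.07 in A549, and 0.23 and -0.08 in H1299. Among the cytoplasmic readers, YTHDF1 had -0.01 and -0.21, YTHDF2 -0.15 and -0.17, and YTHDF3 0.01 and 0.16. limma's camera did not call the list of 24 genes in A549 (adjusted p = 0.423) or H1299 (0.879).

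Among 4 targets known from the study, the receptor tyrosine kinase EGFR had the largest difference. It stood at 155 in A549 shGFP cells and at 91.4 and 94.1 in the knockdown libraries (log2 -0.73, SE 0.21). In H1299 it stood at 82.7 and at 77.6 and 37.0, so that only library 2 was far below the control (log2 -0.61, SE 0.47). WWTR1, the Hippo pathway coactivator TAZ, stood at 601 and at 499 and 597 in A549, and at 201 and at 156 and 201 in H1299. MAPKAPK2, a kinase downstream of p38, stood at 259 and at 314 and 273, and at 233 and at 199 and 202. The DNA methyltransferase DNMT3A stood at 39.7 and at 47.9 and 30.9, and at 121 and at 122 and 107. None passed by limma; the smallest p adjusted over these 4 genes alone was 0.0872, for EGFR in A549. The targets were chosen by the study, so their direction is not independent evidence, and transcript level does not measure translation.

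**Figure D1:**
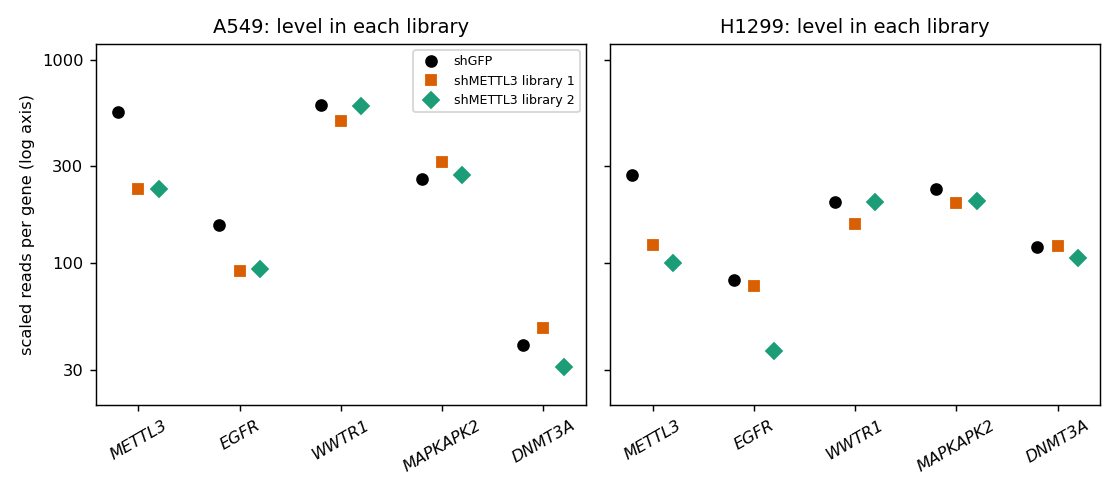
Level of METTL3 and 4 study targets in each library (value as deposited, log axis; shGFP and shMETTL3 libraries 1 and 2 of A549 and H1299). METTL3 stands at 41.6 and 41.7% of shGFP in A549 and at 45.4 and 36.9% in H1299, while WWTR1, MAPKAPK2 and DNMT3A stay closer to it.

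In A549, the gene furthest above the control was IGFBP5 and the gene furthest below it CDH4. IGFBP5, which binds insulin-like growth factors, stood at 2.37 in shGFP cells and at 21.1 and 10.6 in the knockdown libraries (log2 2.25, SE 0.54). SCG2, a protein of secretory granules, stood at 11.6 and at 33.6 and 43.4 (log2 1.64, SE 0.33), and SESN3, a stress-induced inhibitor of mTORC1, at 13.2 and at 48.9 and 35.6 (log2 1.59, SE 0.34). Lower were the cadherin CDH4 (34.7 and 7.14 and 2.81; log2 -2.68, SE 0.58), the neuropeptide precursor VGF (24.7 and 2.5 and 4.06; log2 -2.61, SE 0.46) and the secreted matrix protein OLFML3 (45.8 and 15.0 and 15.0; log2 -1.55, SE 0.31). No gene passed by limma: 0 of 17454 had an adjusted p under 0.05 and 115 an unadjusted p under 0.05, and edgeR called 0 of 16263. Unchanged genes alone would give 5% under an unadjusted 0.05. The test was therefore conservative here, and 0 calls do not show that no gene changed.

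By size alone, 69 genes were at least 2-fold apart from A549 shGFP in both knockdown libraries, 56 higher and 13 lower. Beside those above, the higher ones included ANK3, a membrane skeleton adaptor (3.95 and 22.5 and 9.38), the PI3K inhibitor PIK3IP1 (2.11 and 9.29 and 7.81), the lipid hydrolase FAAH2 (1.58 and 10.0 and 4.69) and the cytokine IL1B (1.05 and 7.14 and 3.44). COLCA2, a colorectal cancer susceptibility gene (0.26 and 9.29 and 2.19), the carnosine synthase CARNS1 (0.26 and 2.86 and 3.13) and the noncoding LINC01085 (2.63 and 12.9 and 10.6) had few reads in the control. The hyaluronan synthase HAS1 (1.43 and 2.5) and the antisense transcript THRB-AS1 (2.14 and 1.56) were listed at 0 in it. Lower were the growth factor IGF2 (5.53 and 1.79 and 1.88), the cytokine receptor IL7R (4.21 and 0.71 and 1.25), ADGRG2, an adhesion G protein-coupled receptor (25 and 11.1 and 10.9), and RAPGEF5, which activates Rap GTPases (7.63 and 2.86 and 1.88). So were the muscle scaffold gene CMYA5 (log2 -1.32), the calcium sensor CALN1 (-1.21), the little-studied C6orf52 (-1.60), the noncoding LINC00960 (-1.26) and METTL3 itself. Simulated libraries without any change gave 187 higher and 117 lower genes by this rule. In them libraries 1 and 2 share 1 control, and the spread was estimated from the difference of libraries 1 and 2. It thus holds any difference between the numbers, so these simulated counts can be too high. The observed count was 11 at a mean of at least 20, so that most of the 69 genes rest on few reads.

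Genes of the cell cycle fell in A549. Of 34 S phase genes, 27 were lower in both knockdown libraries, with medians of -0.27 and -0.18 in libraries 1 and 2 (adjusted p = 1.48e-09 by limma's camera, and adjusted p = 0.848 with an estimated correlation). Among them were the replication factors CDC45 (log2 -0.52) and CDC6 (-0.39) and RRM2, a subunit of ribonucleotide reductase (-0.39). Of 34 G2/M genes, 31 were lower in both (medians -0.17 and -0.25; adjusted p = 1.48e-09, and 0.848 with an estimated correlation). They included CDC20 (-0.36), which activates the anaphase-promoting complex, the checkpoint kinase BUB1 (-0.35) and the mitotic kinase PLK1 (-0.34). These were small shifts: no single member passed over its list alone.

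Lists of energy and protein synthesis were also called as lower in A549, but of these only oxidative phosphorylation had similar medians in libraries 1 and 2. Of 29 genes of oxidative phosphorylation, 21 were lower in both libraries (medians -0.11 and -0.10; adjusted p = 0.00327, and 0.848 with an estimated correlation), led by the complex II genes SDHD (-0.35) and SDHB (-0.33). Without library 1 its adjusted p was 0.0596. Of 42 translation initiation factors, 24 were lower in both (medians -0.19 and -0.02; adjusted p = 0.00253, and 0.848 with an estimated correlation). They included EIF2B3 (-0.44), a subunit of the exchange factor of eIF2, EIF5A (-0.36) and EIF3C (-0.33), a subunit of the eIF3 scaffold. Without library 1 this call was lost (adjusted p = 0.740). Ribosomal protein genes had opposite signs in libraries 1 and 2 at 72 of 78 genes (medians -0.31 and 0.14). Their call as lower (adjusted p = 0.0108, and 0.929 with an estimated correlation) turned to higher without library 1 (adjusted p = 3.72e-07).

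The histone list was called as higher in A549, with the largest change at HIST1H4H (log2 1.06), but no member passed over the list alone. Of 13 measured, 6 were higher in both libraries, and the medians were -0.07 and 0.53 (adjusted p = 0.0214, and 0.848 with an estimated correlation). Without library 2 the direction turned (adjusted p = 0.866). Poly(A) selection captures few replication-dependent histone transcripts.

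Stress and epithelial lists of A549 were called by limma's camera, but not with every setting or library. The stress response list fell (medians -0.20 and 0.04; adjusted p = 0.0328, and 0.848 with an estimated correlation), with the stress transcription factor ATF3 at -0.64 and the cystine transporter SLC7A11 at -0.63. XBP1, a transcription factor of the unfolded protein response, stood at 0.63. Targets of NRF2, the regulator of antioxidant genes, fell (medians 0.05 and -0.28; adjusted p = 0.00224, and 0.848 with an estimated correlation). The epithelial list was called as higher (medians 0.66 and -0.08, adjusted p = 0.0214, and 0.848 with an estimated correlation), with 6 of 19 members higher in both libraries. The largest changes were at the cadherin CDH3 (0.90), the keratin KRT19 (0.87) and the iron-binding LCN2 (0.86), but no epithelial gene passed over the list alone. Without library 1 the stress response call was lost (adjusted p = 0.969) and the epithelial direction turned (adjusted p = 0.199). Without library 2 the NRF2 direction turned (adjusted p = 0.756). At a mean of at least 5 the stress response and epithelial calls were lost (adjusted p = 0.0693 each), and with all 6 libraries in the fit the epithelial call (0.301). Genes of the YAP/TAZ pathway (adjusted p = 0.148) and of ERBB signalling (0.529), and housekeeping genes (0.603), were not called in A549.

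**Figure D2:**
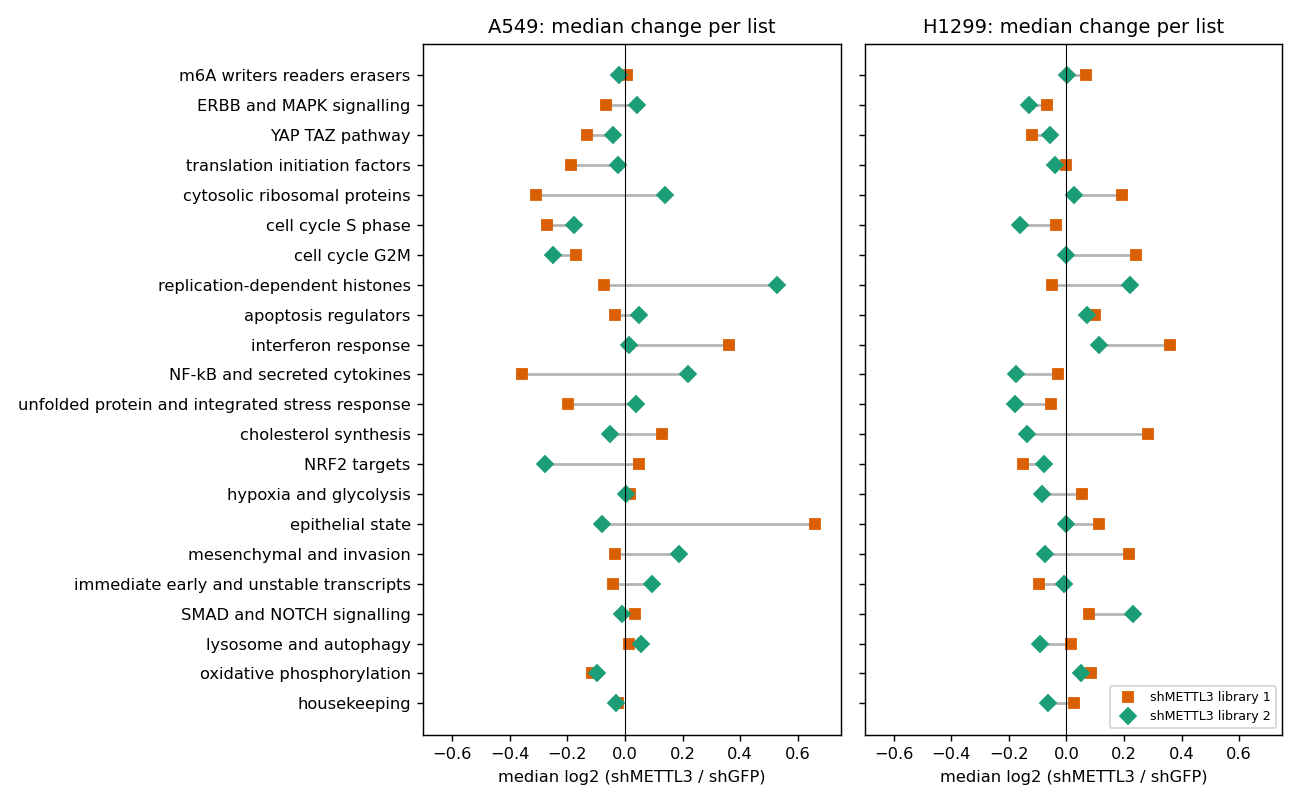
Median log2 ratio of shMETTL3 to shGFP over the members of each gene list, for libraries 1 and 2 of A549 and H1299. Cell cycle lists lie below 0 in both A549 libraries (S phase -0.27 and -0.18), while ribosomal protein genes lie at -0.31 and 0.14.

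In H1299, the gene furthest above the control was NEXN and the gene furthest below it the noncoding TMEM161B-AS1. NEXN, an actin-binding protein, stood at 2.9 in shGFP cells and at 10.9 and 10.4 in the knockdown libraries (log2 1.58, SE 0.34). The ubiquitin ligase adaptor KLHL14 stood at 8.6 and at 28 and 21.4 (1.41, SE 0.34), and the collagen COL1A1 had a log2 change of 1.25 (SE 0.30). No gene passed by limma: 0 of 16470 had an adjusted p under 0.05 and 99 an unadjusted p under 0.05. This too is below the 5% that unchanged genes alone would give, so the test was conservative. edgeR called 1 of 15879 genes, METTL3.

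The rule of size held for 23 H1299 genes, 17 higher and 6 lower. Higher were HS6ST3, which sulfates heparan sulfate (2.4 and 8.9 and 6.8), the growth factor CLEC11A (3.9 and 13.1 and 8.8), the tetraspanin TSPAN13 (4.9 and 13.1 and 11.2) and the transcription factor FOXA3 (2.2 and 5.6 and 7.2). The calcium channel subunit CACNG7 (0.4 and 2.9 and 2.4), the ankyrin repeat gene SOWAHD (0.2 and 2.0 and 2.2), the taste receptor TAS2R30 (0.4 and 2.0 and 2.4) and the chaperone pseudogene HSPA7 (0.6 and 2.7 and 2.4) had few reads, and the last 2 have near copies whose reads they may share. TNFSF13B, the B cell survival factor BAFF, was listed at 0 in the control and at 2.7 and 1.4 in the knockdown libraries. Lower beside METTL3 were the cytokine IL18 (2.2 and 0.2 and 0.6), the sialyltransferase ST3GAL3 (4.5 and 1.6 and 1.2), the elastase CELA3B (2.4 and 0.7 and 0.6) and the noncoding LINC00618 (4.3 and 1.6 and 0.8) and TMEM161B-AS1 (2.9 and 0.4 and 0.2). Simulated unchanged libraries, whose counts can be too high as in A549, gave 44 higher and 26 lower genes. At a mean of at least 20 the observed count was 2.

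Ribosomal protein and mitotic genes rose in H1299. Of 78 ribosomal protein genes, 47 were higher in both libraries (medians 0.19 and 0.03; adjusted p = 0.000158 by limma's camera, and adjusted p = 0.926 with an estimated correlation), led by RPL41 (0.37) and RPS20 (0.32). Of 34 G2/M genes, 17 were higher in both (medians 0.24 and 0.00; adjusted p = 0.0148, and 0.926 with an estimated correlation), among them the kinases AURKA (0.36) and CDK1 (0.35). The S phase list fell, with 17 of 34 lower in both (medians -0.04 and -0.16; adjusted p = 0.00667, and 0.926 with an estimated correlation). In it, the G1/S cyclin CCNE1 stood at -0.77 and RRM2 at -0.34. RNA45S5, the ribosomal RNA precursor and not a ribosomal protein gene, held 23.1, 20.5 and 25.4% of the H1299 total (shGFP, libraries 1 and 2), against 0.266, 0.208 and 0.284% in A549. If the library factors were based on that total, this share moves the scaled values of all other H1299 genes. The median log2 ratio to shGFP was 0.09 in library 1, where the share was below the control. It was -0.04 in library 2, where the share was above the control. An effect on the lists was not tested. Without library 1 the ribosomal (adjusted p = 0.105) and G2/M (0.456) calls were lost, and without library 2 the S phase call (0.211).

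Interferon genes rose and stress genes fell in H1299. Of 29 interferon genes, 15 were higher in both libraries (medians 0.36 and 0.11; adjusted p = 0.00170, and 0.926 with an estimated correlation), among them the antiviral OASL (0.70), IFIT2 (0.59) and the ubiquitin-like ISG15 (0.43). Of 33 stress response genes, 15 were lower in both (medians -0.05 and -0.18; adjusted p = 0.00460, and 0.926 with an estimated correlation). They included asparagine synthetase ASNS (-0.90) and the amino acid transporters SLC7A5 (-0.74) and SLC7A11 (-0.63). NRF2 targets fell (medians -0.15 and -0.08; adjusted p = 0.0187, and 0.926 with an estimated correlation), with the thioredoxin reductase TXNRD1 at -0.43, although the carbonyl and aldo-keto reductases CBR3 (0.77) and AKR1C1 (0.75) stood above the control. Without library 1 all 3 calls were lost (adjusted p = 0.0858 for interferon and stress genes, 0.608 for NRF2 targets). Genes of the YAP/TAZ pathway (adjusted p = 0.0568) and of ERBB signalling (0.0575) were not called; with median centring both were (0.0328 and 0.0220), as they were at a mean of at least 5 (0.0123 and 0.0119). The NF-kB and cytokine list was called at that mean too (adjusted p = 0.00935, against 0.502). Of the marker lists of other cell types with at least 5 measured members, none was called in H1299 (smallest adjusted p = 0.381) or in A549 (0.171). In H1299, fibroblast markers (3 measured) and leukocyte markers (4) were not tested as lists; all 3 fibroblast markers were higher in both libraries, and COL1A1 had an adjusted p of 0.0218 over that list alone, but 0.189 over the mesenchymal and invasion list.

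Across both lines, S phase genes fell the most clearly (adjusted p = 3.05e-09, and 0.647 with an estimated correlation). NRF2 targets (0.000285), stress response genes (0.00142), translation initiation factors (0.00935) and YAP/TAZ pathway genes (0.0477) fell too, and interferon genes rose (0.00391). With an estimated correlation each of these lists had an adjusted p of 0.647, except the initiation factors at 0.797. Not all were called by camera in each line alone. Initiation factors were not called in H1299 (adjusted p = 0.385), where their medians were -0.000646 and -0.0412 in libraries 1 and 2. Interferon genes were not called in A549 (0.105), and YAP/TAZ pathway genes in neither line. Of single genes, 3034 of 15546 (19.5%) lay on the same side of the control in all 4 knockdown libraries; libraries of a line share a control, which raises this share, so no excess is read from it. The largest mean change among these was at VGF (log2 -1.69), which in H1299 stood at 2279 and at 990.0 and 1803. METTL3 (-1.27) and SHC2, a signalling adaptor (1.27), followed; SHC2 stood at 2.63 and at 9.29 and 9.06 in A549, and at 3.9 and at 9.8 and 8.6 in H1299. SESN3 (1.22), the cholesterol hydroxylase CYP46A1 (1.11), the lymphotoxin LTB (1.08), CARNS1 (1.08), SOWAHD (1.05) and TCEAL5, a gene related to elongation factors, had few reads in at least 1 line. EGLN3, a prolyl hydroxylase of the hypoxia response, stood at 102 and at 242 and 262 in A549 and at 3.5 and at 4.7 and 8.4 in H1299. No gene passed in the fit of both lines by limma (0 of 15546, with 374 at an unadjusted p under 0.05) or edgeR (0 of 16586). None passed for a difference between the lines (0, with 49, and edgeR 0). Both 374 and 49 lie below the 5% that unchanged genes alone would give, so these tests were conservative too.

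The changes in knockdown libraries 1 and 2 of a line were only weakly correlated across genes, METTL3 apart. Across genes with a mean of at least 20, their log2 changes correlated at r = -0.0940 in A549 and 0.185 in H1299. Simulated unchanged libraries gave r = 0.488 and 0.499, because libraries 1 and 2 are compared with the same shGFP library. Between the lines, the mean changes correlated at r = 0.193 over 15546 genes and 0.318 at a mean of at least 20. Also at a mean of at least 20, A549 library 1 correlated with H1299 library 1 at r = 0.319, and libraries 2 at 0.372. The crossed pairs gave -0.0265 (A549 library 1 with H1299 library 2) and 0.05 (A549 library 2 with H1299 library 1). The value of 0.318 thus rests mostly on libraries of the same number, and does not show a response common to all knockdown libraries. Genes are not independent replicates, so no p is given.

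**Figure D3:**
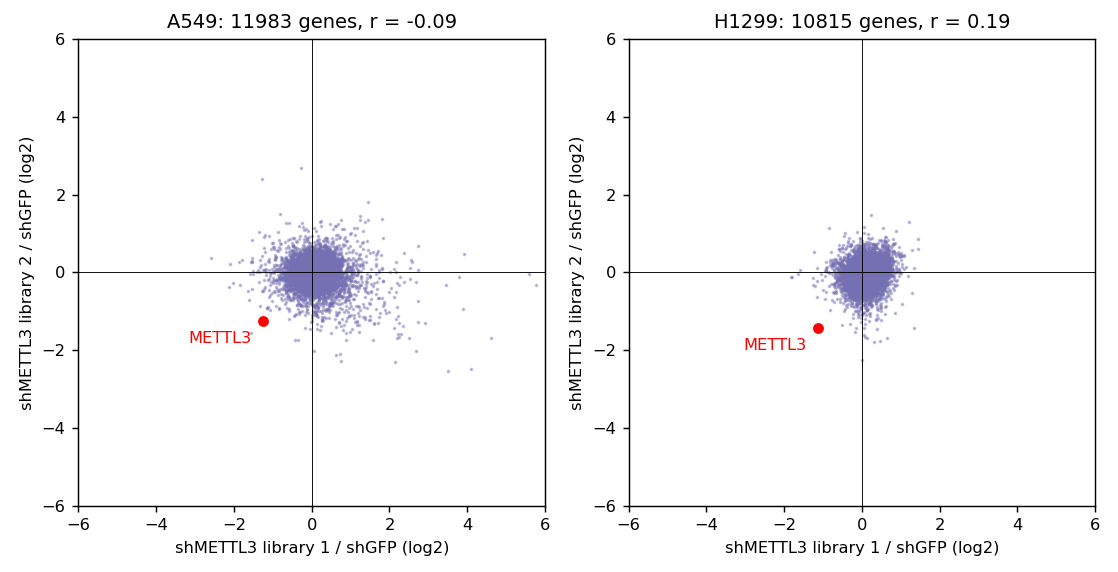
Log2 ratio to shGFP of each gene in shMETTL3 library 2 (vertical) against library 1 (horizontal), for genes with a mean of at least 20 in A549 and H1299. METTL3 (red) is low in both libraries, while all genes together correlate at r = -0.0940 and 0.185.

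In A549, most m6A peaks were found by both immunoprecipitations. Immunoprecipitation 1 has 25074 peaks with a median width of 224 bp, and immunoprecipitation 2 has 26644 with a median of 216 bp. They cover 9.09 and 8.77 Mb. Of the first list, 61.6% (95% interval 61.0 to 62.2) overlapped a peak of the second, and of the second 62.4% (61.9 to 63.0) overlapped the first, against 2.18 and 2.09% after random shifts. The shifts were not kept within transcripts, so the gap can partly reflect that both lists lie in transcripts. Shared peaks were wider: 356 against 149 bp at the median in list 1, and 280 against 145 bp in list 2, where they also had higher scores (115 against 65.8). A wider peak also meets another more easily at an overlap of 1 bp. The labels name a single A549 input, so the agreement of the lists can include what they share through it.

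Most A549 peaks that both immunoprecipitations found were also met by an H1299 peak. The share was 58.5% of these, 55.6% of list 1 and 51.3% of list 2. After shifts, which have the same limit as above, it was 2.98, 2.65 and 2.66%. In the other direction, 25.8% of H1299 peaks overlapped list 1, 22.9% list 2 and 16.9% the peaks found in both. H1299 peaks that overlapped any A549 peak were wider (1103 against 758 bp) and had higher scores (390 against 245) than the rest. At an overlap of 1 bp, a wider peak also meets another more easily. A549 peaks met by an H1299 peak had a median width of 231 against 213 bp in list 1. In list 2 they were narrower (202 against 231 bp) and had higher scores (90.5 against 81.1). H1299 has 39235 peaks with a median width of 795 bp covering 42.0 Mb, which raises the chance of touching an A549 peak. At a 50% reciprocal overlap the share of A549 peaks found in both lists was 12.4%.

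The H1299 peaks were spread differently over the chromosomes. The gene-dense chromosome 19 held 7.37 and 8.47% of the A549 peaks and 3.34% of the H1299 peaks, and chromosome 17 5.98, 6.79 and 2.77%. The gene-poor chromosome 4 held 4.28, 3.52 and 6.53%, and the X chromosome 4.62, 3.79 and 7.14%. No test was made, since each line has its own copy numbers and H1299 has a single list.

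Of the 10 peaks with the highest scores in A549 list 2 and in H1299, 8 each were in all 3 lists. With both lists held to peaks at or above their median score, 37.1% of A549 list 2 overlapped H1299 and 17.9% of H1299 overlapped A549 list 2. In A549 list 2 the highest score, 3199, lay on chromosome 22 at 46316247 to 46319265, followed by chromosome 11 at 1263362 to 1273020 (3100); both were in list 1 and neither in H1299. The other 8 of its top 10, such as chromosome 12 at 125396193 to 125398324 and chromosome 16 at 21845937 to 21848691, were in both other lists. In H1299 the highest scores, 3233, lay on chromosome 1 at 44068827 to 44069907 and on X at 71900307 to 71902861, then on chromosome 7 at 5410007 to 5411258 (3230.1). Of its top 10, 8 were in both A549 lists; the others, on chromosome 4 at 79027183 to 79032397 and at 133865417 to 133871169, were in list 1 alone. In A549 list 2, 15 peaks are tied at 3100, so which of them stand in its top 10 is arbitrary.

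**Figure D4:**
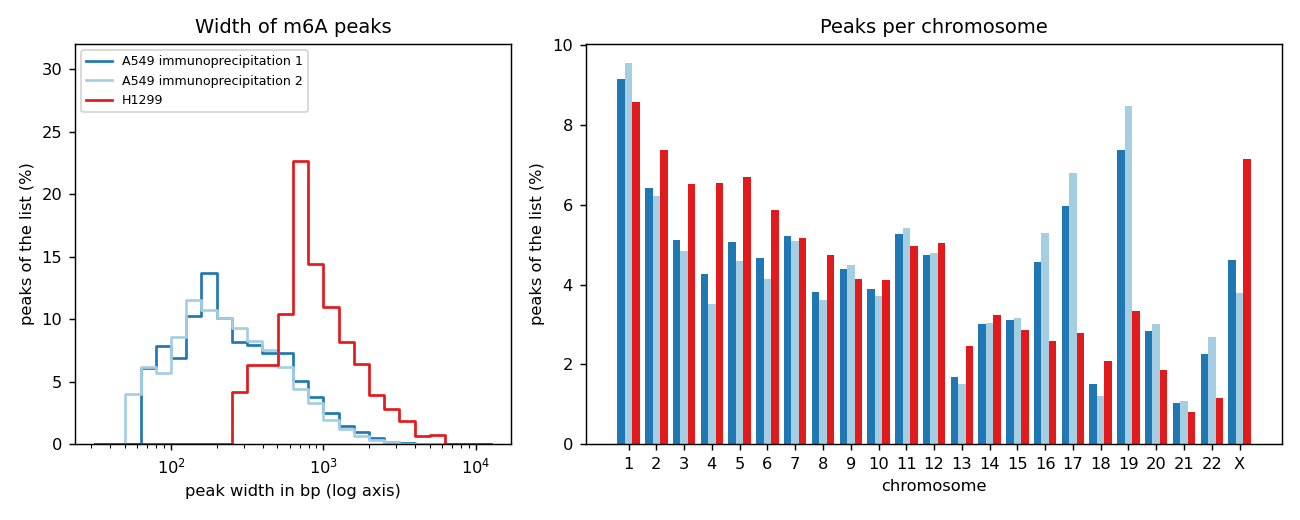
Left, width of m6A peaks in bp (log axis) against percent of the peaks of each list, and right, percent of peaks on each chromosome, for A549 immunoprecipitations 1 and 2 and H1299. H1299 peaks have a median width of 795 bp against 224 and 216 bp, and 3.34% lie on chromosome 19 against 7.37 and 8.47%.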

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

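The tests of a correlated list, of the scaling list by list, and all comparisons of lists between the lines were chosen after seeing the results. The test of a single library, and that of scaling by the number of lists that stay called (3 of 4, which decided nothing), were written before their values were seen.

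Among the lists reported here, what set apart 4 was a difference between the lines: limma's camera on the interaction of line and knockdown called them. The median over the genes of a list of the H1299 log2 change minus the A549 log2 change was 0.21 for ribosomal proteins (adjusted p = 1.57e-06), 0.12 for S phase genes (0.0470), 0.31 for G2/M genes (1.41e-12) and 0.17 for oxidative phosphorylation (0.000340). G2/M genes were lower in 31 of 34 cases in both A549 libraries and higher in 17 of 34 in both H1299 libraries. Each list had an adjusted p of 0.994 with an estimated correlation.

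Members of these lists may vary together between libraries whatever the knockdown, and this stays open. With an estimated correlation 0 of the 4 lists stayed called. However, camera called no list in any comparison with that setting (smallest adjusted p = 0.647, over both lines), so the loss cannot decide. Scaling by 1 factor per library is an unlikely cause of the medians of ribosomal proteins, G2/M genes and oxidative phosphorylation. With median centring these were 0.18, 0.29 and 0.15, against 0.21, 0.31 and 0.17. Their calls stayed (largest adjusted p = 0.000788), but camera compares a list with all other genes, which centring moves alike. Such strong calls could therefore hardly be lost. Scaling that depends on the level of a gene was not tested. For S phase genes it stays open whether 1 factor per library was the cause. Their median moved from 0.12 (quartiles 0.06 and 0.18) to 0.0896 (0.03 and 0.15). This took a call close to the threshold past it (adjusted p = 0.0681), as did the pseudocount 0.1 (0.0533). Reliance on 1 knockdown library stays open too: at the fewest, 2 lists stayed called with a library left out; without A549 library 1 the ribosomal difference turned negative (adjusted p = 0.212) and the S phase difference was lost (0.563), as it was without H1299 library 1 (0.438), while G2/M and oxidative phosphorylation stayed called in all 4 cases. A biological difference between the lines was not tested, as each line has a single control library.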

How the results depend on the processing

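Tests on recovered reads with edgeR, the mean of at least 20, the number term, and the lists that differ between lines were chosen after seeing the data; the other alternatives were written before the data were examined. Of 323 named values, 18 settings gave 2804 with the same direction and side of the threshold, 37 weaker and 4 reversed. The counts of 0 genes in A549, in H1299, in both lines and between the lines held under every planned setting, as did all directions of METTL3. With edgeR, H1299 had 1 call, METTL3 (log2 -1.31, FDR 0.00172). The replicate block could only be a number term over both lines, since shGFP carries no number and libraries 1 and 2 share only a number; it gave 1 call, METTL3 (-1.27, adjusted p = 0.0173), and with edgeR 1 call, METTL3 (-1.29, FDR 0.00814). With that term histones were also called over both lines (adjusted p = 0.0247 against 0.0929). Genes apart between the numbers 1 and 2 were 257, but 407 at a mean of at least 20, 402 with edgeR and 484–1377 with a library left out. For number 1 alone edgeR called 24 in place of 8, and for number 2 a mean of at least 20 gave 20 in place of 8. By the rule of size, A549 had 227 genes with the pseudocount 0.1, 29 at a mean of at least 5, 11 at a mean of at least 20, 428 at 1.5-fold and 517–849 with a library left out. H1299 had 137, 9, 2, 295 and 221–251. The smaller pseudocount, the lower fold and the loss of a second library each ask less of a gene. The correlation of changes between the lines was 0.318 at a mean of at least 20. With an estimated correlation 0 lists were called in A549, 0 in H1299 and 0 between the lines. With a library left out, 1–7 lists were called in H1299 and 3–10 between the lines. In A549, leaving out a library reversed ribosomal proteins (adjusted p 1.66e-20–3.72e-07), histones (1.79e-07–0.866), NRF2 targets (7.36e-08–0.756) and epithelial genes (0.00105–0.199); the end with the larger p is the reversed direction. At 50% reciprocal overlap the shared peaks were 52.96% of A549 list 1 and 49.8% of list 2; of H1299, 5.24% with list 1, 4.29% with list 2 and 4.89% with the peaks in both; and of list 1, list 2 and the peaks in both, 8.20, 6.31 and 12.4% with H1299. Among peaks at or above the median score the same values were 43.2, 83.7, 33.3, 17.9, 16.5, 39.5, 37.1 and 39.9%; list 1, without scores, stayed whole. The stricter overlap asks for similar widths. In the score setting the partner list was cut as well, unless it was list 1, which leaves fewer peaks to meet. For all other values that moved, the cause was not tested. Not run for want of an hg19 annotation or genome were the alternatives for methylated genes, their change in level, peak position and motifs. A single control library and 1 residual degree of freedom limit every test within a line, and depth limits genes of a few reads.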

Other observations

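The tests in this part were chosen after seeing the results, except that of H1299 peaks from background, which was written before its value was seen.

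A few genes of the lists stood out over both lines when adjusted over the list alone. SLC7A11, which imports cystine for glutathione synthesis, had log2 changes of -0.63 and -0.64 in A549 libraries 1 and 2 and -0.75 and -0.51 in H1299 (mean -0.63, SE 0.12; limma adjusted p = 0.0189 over the NRF2 list alone). TGFBR2, the TGF-beta receptor, was higher in all 4 libraries (mean 0.63, SE 0.12; 0.0104 over the SMAD and NOTCH list alone), as was FZD7, a WNT receptor (mean 0.71, SE 0.14; 0.0104). The collagen COL1A1 was higher in all 4 as well (mean 0.84, SE 0.22), but did not pass over the mesenchymal and invasion list. It was the only fibroblast marker measured in both lines, so its limma p of 0.00524 over that list is in effect unadjusted. Over all genes each had an adjusted p of 0.999983.

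Libraries with the same number resembled each other across the lines. Changes in A549 library 1 correlated with H1299 library 1 at r = 0.319 across genes with a mean of at least 20, and those of libraries 2 at 0.372, while the crossed pairs gave -0.0265 and 0.05. In a fit of all 6 libraries, limma called 257 genes as different between the numbers, 191 higher in number 1 and 66 higher in number 2. Each had the same direction in both lines, but the fit favours this, as opposite differences count as spread in it. By size alone, 33 of 10099 genes with a mean of at least 20 differed 2-fold between the numbers in the same direction in both lines. In opposite directions it was 1. In place of 257, the fit called 407 genes at a mean of at least 20, and edgeR called 402. With a knockdown library left out, 1 of the numbers is present in a single line. Such fits do not test a difference in both lines. FN1, the matrix protein fibronectin, stood at 882 in A549 shGFP cells and at 5894 and 532 in libraries 1 and 2, and in H1299 at 17.1 and at 40.0 and 16 (log2 difference 2.37, adjusted p = 0.0332). The sodium channel SCN9A differed by 2.02 (0.00361) and the transmembrane protein TMEFF2 by 2.64 (0.00769).

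Single genes were low with a single number in both lines. PMVK, an enzyme of cholesterol synthesis, stood at 268 and at 260.4 and 97.2 in A549, and at 278 and at 302 and 85.8 in H1299, and the ribosome receptor RRBP1 at 680 and at 800.4 and 259, and at 544 and at 548 and 114. TXNDC5, a disulfide isomerase, was low with number 1 instead (664 and 293 and 700.0 in A549, 947 and 267 and 872 in H1299), though it shares sequence with the read-through BLOC1S5-TXNDC5. limma called 8 genes for number 1 and 8 for number 2, and METTL3 was the only gene in both; edgeR had 3 in both, METTL3, MUC5AC and MUC5B, of which 1, METTL3, had the same direction. By limma's camera, cholesterol synthesis (adjusted p = 3.69e-05) and epithelial genes (0.0193) were higher in number 1 than in number 2, and histone (2.72e-06) and immediate early genes (0.0127) lower, each at 0.771 with an estimated correlation. Ribosomal protein (8.22e-09), initiation factor (0.00422) and NF-kB and cytokine genes (0.0158) were lower too, each at 0.906 with it.

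The hypothesis was that each number is another hairpin with its own off-target genes. Off-target hairpins lower their targets, but such falls can raise other genes: of the called genes that depart more from shGFP in number 2, 87.6% (106 of 121) depart by a fall, and of those in number 1 37.5% (51 of 136), so this stays open. The test was run on these 257 genes alone, on all at first (61.1% falls), and split by number after the opposite directions were seen. Unequal METTL3 transcript levels are an unlikely cause in A549, where METTL3 differed between the numbers by -0.00471 on the log2 scale. In H1299 the log2 difference was 0.29, so unequal knockdown stays open there. The data hold no METTL3 protein level and no m6A level of knockdown cells. Low depth stays open: 87.9% of the called genes have a mean of at least 20, but so have 10099 of the 15546 tested genes. Genes with more reads are also more easily called, so this share cannot decide. A preparation shared by libraries of the same number could give the same correlation of the differences across lines (r = 0.372), and the labels name no batch, so this stays open; no biological explanation was tested.

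H1299 peaks were wider than A549 peaks and spread more evenly over the chromosomes. Other calling settings or fragments could give the width, as the H1299 peak was 5.21 times as wide at the median in 13961 overlapping pairs with A549 list 1. Weak peaks are an unlikely source of the low share on chromosome 19: among H1299 peaks without an A549 partner, the share on chromosome 19 was lower in the 6675 peaks with the highest scores than in the 6675 with the lowest, by -2.70 points (1.14 against 3.84%). Background outside transcripts was tested by the distance to an even spread, and its value, 4.93 points more distance in the highest-score peaks, met the prediction; it is left open because that distance has no direction and the strong peaks moved away from chromosome 19. A signal that depends on base composition is consistent with shared peaks, whose share on chromosomes 16, 17, 19, 20 and 22 changed by -8.66 points from the 3024 lowest-score to the 3024 highest-score peaks in H1299 and by 16.4 points in A549 list 2 (3403 peaks at each end), but base composition was not measured, and no biological explanation was tested.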
